A study of Homo sapiens with 4 samples.

How the data were processed

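RNA-seq libraries of FT190 cells were compared, 2 from cells with the PLKO control vector and 2 from cells expressing an shRNA against SMARCA4. Cells were grown in RPMI medium with serum, RNA was extracted with silica columns, and libraries were made from total RNA with a SMARTer mRNA kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles.

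The deposited table holds raw counts per gene, made by the authors with HOMER's analyzeRepeats over exons of GENCODE release 45 on hg38, per the file header. The command in the header counted reads on both strands, kept 1 transcript per gene and applied no normalization, so overlapping and antisense genes share reads. Reads were aligned with STAR 2.6.1c, and the notes also name DESeq2 1.19.38, per the submitters' processing notes. The header command names 6 libraries. The deposited table holds value columns for the 4 samples only, and these were used. Counts summed to 33641343, 32618516, 28536665 and 27137414 in control 1, control 2, shRNA library 1 and shRNA library 2, with 29151, 29231, 28618 and 28472 genes detected.

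All 63241 genes entered the summed counts above and the shares of counts given below. Genes were kept by filterByExpr with a count minimum of 10, which left 18781 for testing and removed 44460. Library totals for scaling, CPM values and tests were then taken over the genes kept. Counts were scaled by trimmed means of M values (factors 0.976, 0.990, 1.02 and 1.02) and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM values are counts divided by the scaled library total in units of 1e+06, computed here from the deposited counts. The biological coefficient of variation was 0.0413. With 2 libraries against 2, an exact permutation test of any value cannot go below p = 0.33, so no such test was run.

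Before the data were examined, 37 gene lists were fixed: BAF subunits, pausing and elongation, R-loop regulators, homologous recombination, end joining, Fanconi anaemia, DNA replication, mitosis, p53 targets, interferon-stimulated, NF-kB, immediate-early, YAP and TEAD, TGF-beta, epithelial, mesenchymal, collagen and matrix, integrins and adhesion, matrix proteases, secretory, ciliated, immune, endothelial and fibroblast or smooth muscle markers, cholesterol, glycolysis, hypoxia, nuclear oxidative phosphorylation, unfolded protein response, heat shock, ribosomal proteins, replication histones, mitochondrially encoded, Polycomb and other chromatin genes, calcium, receptor tyrosine kinases, and Wnt and Notch. Some genes stand in more than 1 list. The 36 lists with at least 5 tested members were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, with adjustment over lists. Counts of members past the threshold are given over all genes tested and adjusted over the list alone.

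The rule for named genes was also fixed before the data were examined. It names 10 genes always, among them SMARCA4, SMARCA2, ARID1A, BRCA1, BRCA2, NELFE, CDK9 and RNASEH1, and up to 3 members per list with the smallest adjusted p. It also names the 10 protein-coding genes with the largest rise and the 10 with the largest fall among those past the threshold, with a mean of at least 5 CPM and groups that do not overlap. Not every gene that the rule picks is reported here. Members named beyond it, to spell out a small count or as further examples, were chosen after their values were seen.

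The gene test was checked on simulated counts of 18511 genes drawn with the real means and library sizes. It recovered 26.0% of genes changed 1.2-fold, 58.3% at 1.5-fold, 92.0% at 2-fold and 98.0% at 4-fold, and 5.59% of its calls were unchanged genes. Here 50, 48, 50 and 49 genes were changed by these folds and 18314 were not, against 29.7% of genes called in the data. The shares recovered need not hold for the data. With 1 list moved, camera called 1 list. Genes were drawn independently there, so this does not show how often camera calls lists whose members are correlated. A search of 7-mers regressed log2 fold changes on the presence of each 7-mer in the 3' UTR, with 100 permutations. It took protein-coding genes other than SMARCA4 with a mean of at least 5 CPM and a 3' UTR of at least 50 bases. The search recovered a planted 7-mer as the leading one. Sequences, GC content and lengths came from GENCODE release 29, which is not the release of the counts. A GC content and length were found for 97.0% of tested genes. The transcript used held neither 3' UTR nor coding part for genes such as RPL23, ACTA2, TPM2 and NELFE, and no 3' UTR for BRCA1. A gene with no 7-mer reported may therefore still carry 1.

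Alternatives fixed beforehand were other scaling (RLE, upper quartile, library totals), no filter or a 1 CPM filter, DESeq2 1.42.0, limma-voom, a replicate block, each library left out, thinning to the smallest library, protein-coding genes alone, a threshold of 0.01, glmTreat against 1.5-fold, camera with an estimated correlation, and fry. With an estimated correlation, camera takes its degrees of freedom from the libraries. With 2 libraries per group these are few, so a list can fail that test even where nearly all members moved. Removal of GC and length trends, and a test without genes carrying the leading 7-mers, were added after the data were seen. Scripts ran in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures used matplotlib 3.10.9.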

Results

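RNA was sequenced from FT190 cells, a human epithelial line labelled as ovarian and known as an immortalised line from the secretory epithelium of the fallopian tube. 2 libraries came from cells carrying the PLKO control vector and 2 from cells expressing a short hairpin RNA (shRNA) against SMARCA4, the ATPase of the SWI/SNF (BAF) chromatin remodelling complexes. The labels name 1 hairpin treatment, and the sample titles give only its target. Total counts were 33641343 and 32618516 in the controls and 28536665 and 27137414 in the shRNA libraries. Mitochondrially encoded transcripts took 3.31% and 4.06% of counts in control libraries 1 and 2, and 3.19% and 3.08% in the shRNA libraries. The 10 most abundant genes took 5.22% and 5.35% of counts in the controls and 4.54% and 4.51% in the shRNA libraries. Counts of the 2 controls differed by more than sampling noise (chi-square 6.94 per degree of freedom), as did those of the 2 shRNA libraries (1.96), so each library counted as 1 replicate. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

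The comparison of shRNA with control cells asked which transcripts change when SMARCA4 is depleted, in a study whose title concerns RNA polymerase II pausing, R-loops and BRCA1-dependent repair. SMARCA4 itself (ENSG00000127616.22, chromosome 19, 10961030 to 11062273 on the plus strand of hg38) stood at 167 ± 6.00 CPM in controls and 35.2 ± 1.65 CPM in shRNA cells (SD, n = 2 in each group). The 2 control libraries held 171 and 162 CPM and the 2 shRNA libraries 34 and 36.3 CPM. This was a 4.74-fold lower level, a log2 fold change of -2.24 (SE 0.052), with adjusted p = 1.86e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Below, a value after a gene symbol is the log2 fold change of shRNA over control cells with its standard error, from 2 libraries per group. Genes are said to have risen or fallen only where the adjusted p of that test was under 0.05.

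Other BAF subunits moved in both directions. Of 27 subunits tested, 8 rose and 6, SMARCA4 included, fell (10 higher and 6 lower adjusted over the list alone). SMARCC1 (-0.91 ± 0.041), a scaffold subunit, fell most after SMARCA4, from 292 to 155 CPM, and PHF10 (-0.35 ± 0.044), SMARCD1 (-0.33 ± 0.049) and SMARCD3 (-0.50 ± 0.11) fell by less. The alternative ATPase SMARCA2 (-0.21 ± 0.047) also fell, with adjusted p = 0.0104 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, a call lost with DESeq2, with no filter on low counts or without either shRNA library. BCL7A (0.78 ± 0.062), DPF3 (0.70 ± 0.091) and ARID2 (0.35 ± 0.046) rose, and the DNA-binding subunit ARID1A stood at 0.13 ± 0.053 and did not pass the test (adjusted p = 0.104 by edgeR's quasi-likelihood test), though it did with library totals, upper-quartile factors, the replicate block, GC and length trends removed, or without control 1. Camera did not call the list (adjusted p = 0.560), and its direction, higher, went with the median (0.05) and against the mean (-0.04). The 7-base sequence ATAGTGA, the 7-mer of 3' untranslated regions (UTRs) most closely tied to lower levels across genes, occurred 3 times in the coding part of SMARCC1, 1 time in that of SMARCA4, of ARID2 and of ARID1A, and 1 time in the 3' UTR of PHF10. The next 2 such 7-mers, TAGTGAA and GATAGTG, overlap it. Of genes named here with no ATAGTGA in the 3' UTR, at least 1 of these 2 stood in the 3' UTR of SMARCC1, SMARCD1, SMARCA2, LOX, LUM, DKK3, BRIP1, RAD51C, FANCG, FANCI, MCM4, CCNT2 and XBP1, which fell, and of EMP1, ITGA2, AEN, FBN1 and ERAP1, which rose.

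**Figure D1:**
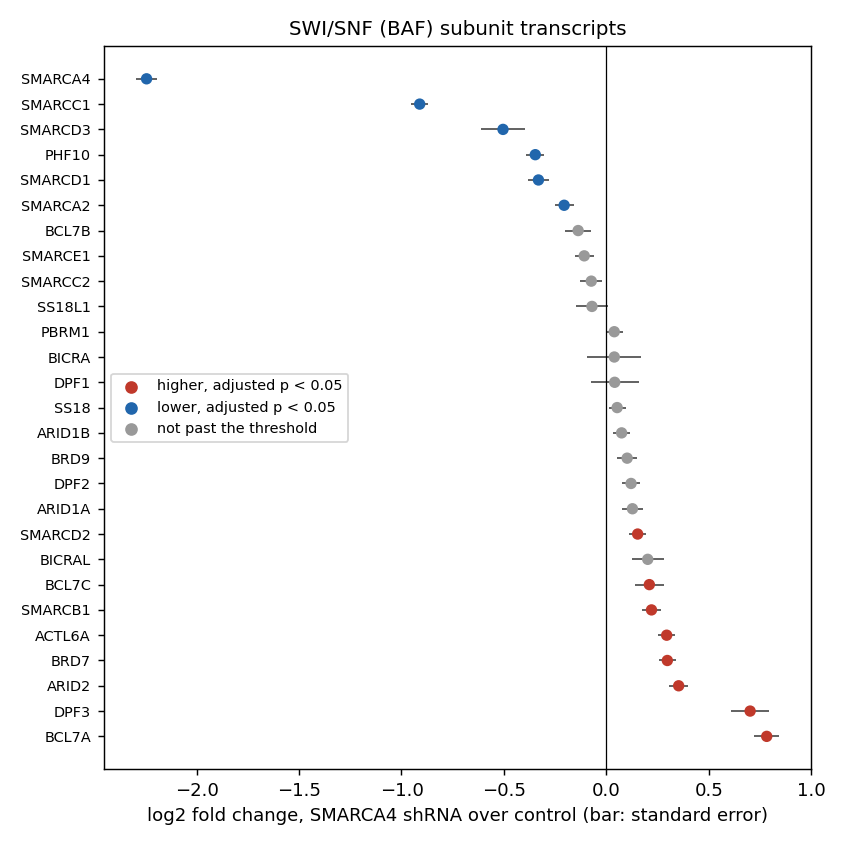
Log2 fold change of shRNA over control cells (x axis) for the 27 BAF subunit transcripts tested (y axis), with bars for the standard error from 2 libraries per group. SMARCA4 lies at -2.24 and SMARCC1 at -0.91, while the other subunits lie between -0.50 and 0.78.

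Of 18781 genes tested, 2596 rose and 2976 fell, 29.7% of those tested. Most changes were small: the median absolute log2 fold change of these 5572 genes was 0.37, and 1622 of them changed by less than 1.2-fold. A log2 fold change of at least 1 was reached by 192 genes that rose and 366 that fell. Among 13680 protein-coding genes 2299 rose and 2621 fell, and among 3907 long non-coding RNAs 252 rose and 291 fell. The groups did not overlap in 65.9% of genes tested, where chance gives 0.33 of genes for 2 against 2. Genes that rose made up 46.6% of the calls with the main scaling (trimmed mean of M values) and 59.5% with library totals alone. A test against a 1.5-fold change (glmTreat) called 295 genes, 93 higher and 202 lower.

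By the fixed rule, which takes protein-coding genes with a mean of at least 5 CPM and groups that do not overlap, the largest rise was in ANGPTL4, a secreted inhibitor of lipoprotein lipase, at 1.97 ± 0.371 CPM in controls and 15.1 ± 0.192 CPM in shRNA cells (SD, n = 2), 7.67-fold. It was followed by the cytokine IL6 (1.86 ± 0.096), the mitochondrial nucleotide kinase CMPK2 (1.79 ± 0.16), the hyaluronan-degrading factor CEMIP (1.74 ± 0.099), the chemokine CCL5 (1.67 ± 0.14), the interferon-induced GTPase GBP4 (1.66 ± 0.16), the hyaluronan synthase HAS2 (1.42 ± 0.12), EMP1 (1.41 ± 0.049), DHRS2 (1.41 ± 0.15) and the collagen receptor subunit ITGA2 (1.40 ± 0.079). By the same rule the largest falls were in NPPB, which encodes the natriuretic peptide precursor B (-2.93 ± 0.37), and the smooth muscle protein CNN1 (-2.39 ± 0.17). SMARCA4, TLL1 (-2.09 ± 0.22), EPPK1 (-2.08 ± 0.17), AIF1L (-1.92 ± 0.085), the pro-apoptotic BH3-only gene BMF (-1.86 ± 0.26), GXYLT1 (-1.70 ± 0.046), RASD2 (-1.61 ± 0.17) and ZCCHC24 (-1.60 ± 0.13) came next. Their adjusted p-values by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment lay between 1.86e-07 and 8.37e-04. The 2 control libraries differed from each other in NPPB (12.1 and 6.01 CPM) and BMF (9.33 and 16.6 CPM), with 1.28 and 1.09 CPM, and 3.56 and 3.55 CPM, in the shRNA libraries. ATAGTGA occurred 3 times in the 3' UTR of GXYLT1, 1 time in that of TLL1 and of ZCCHC24, and 1 time in the coding part of CEMIP.

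**Figure D2:**
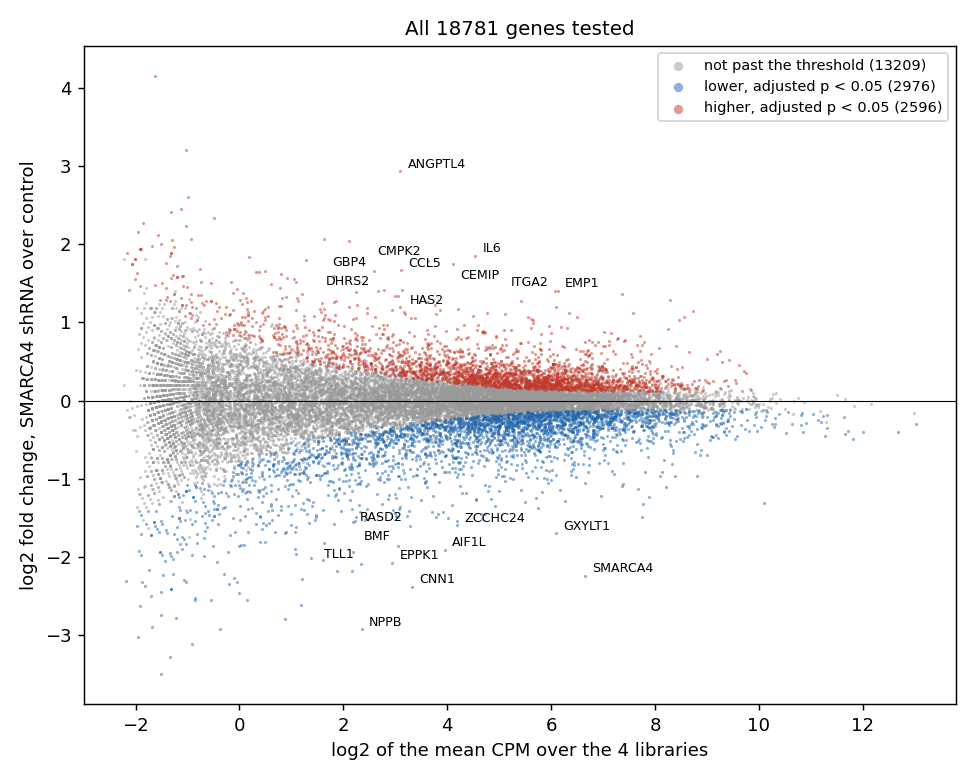
Log2 fold change of shRNA over control cells (y axis) against the log2 of the mean CPM over the 4 libraries (x axis), with 1 point for each of the 18781 genes tested. The 2596 genes that rose are red, the 2976 that fell are blue, and the named points are the 10 protein-coding genes with the largest rise and the 10 with the largest fall by the fixed rule.

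The genes of the processes in the series title changed by small amounts and in both directions. Of 36 factors of polymerase pausing and elongation, 8 rose and 9 fell (9 higher and 11 lower adjusted over the list alone). The P-TEFb inhibitor HEXIM1 (-0.39 ± 0.054) and the cyclin CCNT2 (-0.36 ± 0.058) fell, while LARP7 (0.31 ± 0.047), a protein of the 7SK particle that holds P-TEFb inactive, rose. The P-TEFb kinase CDK9 stood at 0.00 ± 0.063 and the pausing factor subunit NELFE at 0.14 ± 0.050, neither past the test (adjusted p = 1.000 and 0.0625 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Camera did not call this list (adjusted p = 0.863), and NELFE passed with library totals, upper-quartile factors, a 1 CPM filter, the replicate block or protein-coding genes alone, and without control 1.

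Of 27 R-loop regulators, 6 rose and 1 fell (11 higher and 1 lower adjusted over the list alone). TOP1 (0.26 ± 0.041), the topoisomerase that relaxes supercoils behind the polymerase, was among those that rose. The RNA helicase DDX39B (-0.22 ± 0.046) fell, a call lost without shRNA library 1, and the locus overlaps a read-through gene, so its counts are uncertain. RNASEH1, which degrades the RNA of hybrids, stood at 0.08 ± 0.054 (adjusted p = 0.295 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and passed only in the fit without control 1. By camera the list was not called (adjusted p = 0.130), but it was called as higher with library totals alone (adjusted p = 0.0316) and with no filter on low counts (adjusted p = 0.0433), within a range of 0.0316 to 0.787 over all settings.

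BRCA1 transcripts did not differ detectably between the groups (-0.03 ± 0.045, adjusted p = 0.691 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), at 93.6 ± 0.0230 CPM in controls and 91.8 ± 3.61 CPM in shRNA cells (SD, n = 2). Of 41 homologous recombination genes, 9 rose and 4 fell (9 higher and 5 lower adjusted over the list alone). The helicase BRIP1 (-0.52 ± 0.046), RAD51C (-0.40 ± 0.052) and the nuclease cofactor RBBP8 (-0.20 ± 0.041) were among those that fell, and the kinase ATM (0.33 ± 0.043) rose. BRCA2 (0.22 ± 0.070) rose by a small amount (adjusted p = 0.0442 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). This BRCA2 call was lost with DESeq2, with no filter on low counts, without control 2 or without shRNA library 1. In the end-joining list, 5 of 20 genes rose and 3 fell (5 higher and 3 lower adjusted over the list alone): the ligase cofactor XRCC4 (0.48 ± 0.059) rose, and NHEJ1 (-0.65 ± 0.100) and the Ku subunit XRCC5 (-0.26 ± 0.038) fell. Among 16 Fanconi anaemia genes, 4 fell and 1 rose (1 higher and 4 lower adjusted over the list alone), FANCD2 (-0.49 ± 0.051), FANCG (-0.30 ± 0.065), FANCI (-0.20 ± 0.043) and WDR48 (-0.22 ± 0.049) against FANCC (0.27 ± 0.069). The calls of FANCI and FANCG were lost without shRNA library 2, and that of FANCI with no filter on low counts. Camera called none of the 3 lists (adjusted p = 0.238, 0.245 and 0.779). The Fanconi list had a median of 0.01 with a mean and a test direction that were lower. The ATAGTGA 7-mer occurred 1 time in the 3' UTR of ATM, NHEJ1 and WDR48 and 1 time in the coding part of XRCC5 and FANCI.

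Interferon-stimulated genes rose together. Of 37 tested, 35 rose and 0 fell (35 higher and 0 lower adjusted over the list alone), with a median log2 fold change of 0.77. The antiviral proteins IFIT2 (1.37 ± 0.064) and IFIT5 (0.77 ± 0.046) and the RNA sensor IFIH1 (1.12 ± 0.071) led by adjusted p, and IFIT2 went from 92.0 ± 2.97 to 238 ± 22.9 CPM (SD, n = 2). The 2 members not past the test were STAT2 (0.17 ± 0.094) and IFI27 (0.07 ± 0.068), named after their values were seen, as were members below that complete a small count. Camera called the list as higher (adjusted p = 1.47e-22). It was not called by camera with an estimated correlation (adjusted p = 0.782), a setting with little power at 2 libraries per group. Nor was it called by fry (adjusted p = 0.088 by fry). Relative to the mean of the controls, the list's median was -0.06 and 0.06 in the controls, 0.67 in shRNA library 1 and 0.92 in shRNA library 2. IFIT5 carried ATAGTGA 1 time in its 3' UTR.

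**Figure D3:**
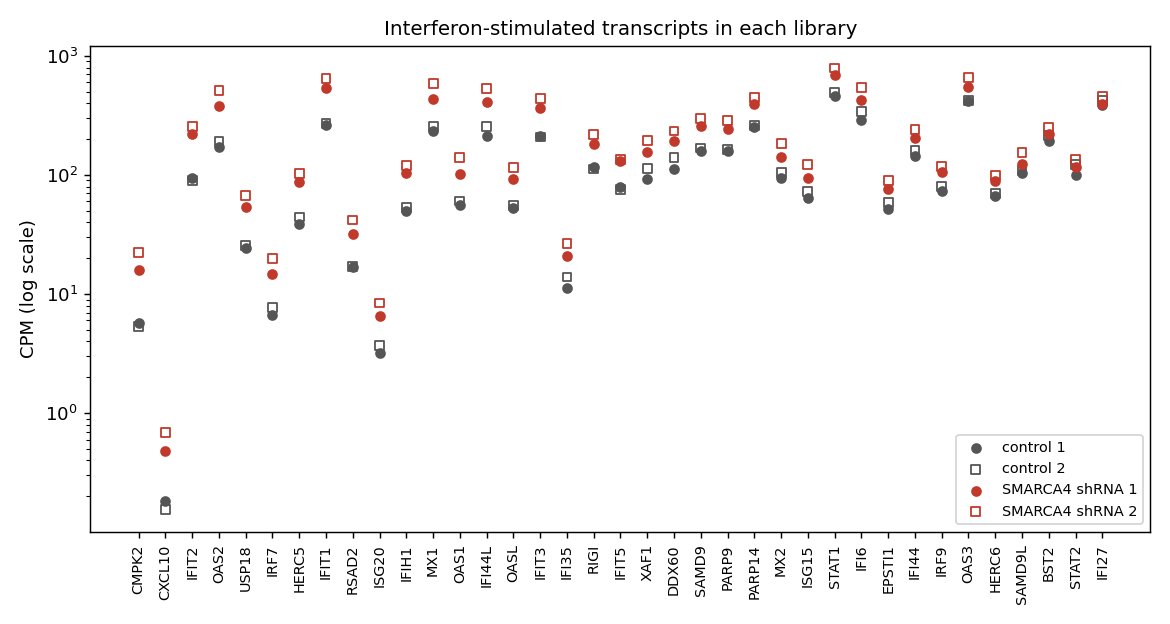
CPM on a log scale (y axis) of 37 interferon-stimulated transcripts (x axis, ordered by fold change) in each of the 4 libraries. Grey marks controls and red marks shRNA libraries, with 1 point per library. The groups lie apart for IFIT2, at 94.1 and 89.9 CPM in the controls and 222 and 254 CPM in the shRNA libraries.

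Inflammatory targets of NF-kB rose more often than they fell. Of 26 tested, 13 rose and 3 fell (15 higher and 3 lower adjusted over the list alone), with a median of 0.41. IL6 and the adaptor TRAF1 (1.11 ± 0.086) rose. The cytokine IL11 (-0.86 ± 0.077) and 2 negative regulators of inflammatory signalling, TNFAIP3 (-0.41 ± 0.072) and ZC3H12A (-0.63 ± 0.12), fell. Among 31 immediate-early and AP-1 genes, 11 rose and 5 fell (13 higher and 6 lower adjusted over the list alone). MYC (0.70 ± 0.049) and DUSP5 (0.61 ± 0.056), a phosphatase of ERK, rose, while SRF (-0.89 ± 0.084), JUNB (-0.37 ± 0.058), JUND (-0.32 ± 0.062), IER5 (-0.23 ± 0.058) and DUSP4 (-0.30 ± 0.092) fell. Camera called both lists as higher (adjusted p = 2.94e-04 and 0.0433), and neither with an estimated correlation (adjusted p = 0.777 with an estimated correlation for each). Fry also called neither (adjusted p = 0.0705 and 0.088 by fry). The immediate-early call was lost with library totals (adjusted p = 0.0604), a 1 CPM filter (0.0778), protein-coding genes alone (0.082) or without genes carrying the leading 7-mers (0.0998). DUSP5 carried ATAGTGA 1 time in its 3' UTR.

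Transcripts of glycolysis were lower. Of 22 tested, 16 fell and 2 rose (4 higher and 17 lower adjusted over the list alone), with a median of -0.31. The neuronal-type enolase ENO2 (-1.15 ± 0.055), the aldolase ALDOA (-0.46 ± 0.037) and the pyruvate dehydrogenase kinase PDK1 (-0.77 ± 0.069) fell, and the glucose transporters SLC2A3 (0.49 ± 0.081) and SLC2A1 (0.17 ± 0.041) rose. Of 20 hypoxia targets, 8 fell and 3 rose (3 higher and 8 lower adjusted over the list alone): the collagen cross-linking enzyme LOX (-1.38 ± 0.050) and PDK1 fell, and ANGPTL4, SLC2A1 and the growth factor VEGFA (0.28 ± 0.083) rose. Camera called both lists as lower (adjusted p = 1.70e-06 and 0.0398), but not with an estimated correlation (adjusted p = 0.777 and 0.787 with an estimated correlation). The hypoxia call was lost with a 1 CPM filter (adjusted p = 0.0778), with protein-coding genes alone (0.0781) and without genes carrying the leading 7-mers (0.677), and PDK1 carried ATAGTGA 2 times in its 3' UTR.

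All 13 mitochondrially encoded transcripts had log2 fold changes below 0, from -0.42 to -0.16, and 9 of them fell (0 higher and 12 lower adjusted over the list alone), among them MT-ND1 (-0.34 ± 0.057), MT-ND2 (-0.25 ± 0.045) and MT-CO3 (-0.41 ± 0.081), the last not past the test with no filter on low counts. The count of 9 was 2 with no filter on low counts and 4 with DESeq2. The median of all 13 was -0.30, and it was -0.16 without control 2 and -0.44 without control 1. Camera called the list as lower (adjusted p = 1.21e-04), but not with an estimated correlation (adjusted p = 0.787 with an estimated correlation). Of 41 nuclear genes of oxidative phosphorylation, 3 rose and 6 fell (3 higher and 4 lower adjusted over the list alone), led by ATP5PO (-0.31 ± 0.042), NDUFS1 (-0.24 ± 0.041) and COX4I1 (-0.17 ± 0.039), without a call by camera (adjusted p = 0.925). The list's median lay above 0 and its mean and test direction below. The COX4I1 call was lost without either shRNA library, and NDUFS1 carried ATAGTGA 2 times in its 3' UTR. In the cholesterol list 4 of 25 genes rose and 11 fell (5 higher and 11 lower adjusted over the list alone; camera adjusted p = 0.175): the sterol carrier STARD4 (-0.58 ± 0.066), with ATAGTGA 1 time in its 3' UTR, and the synthesis enzymes LSS (-0.46 ± 0.054) and TM7SF2 (-1.06 ± 0.14) fell.

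Mesenchymal and contractile transcripts were lower. Of 23 mesenchymal genes, 13 fell and 2 rose (2 higher and 14 lower adjusted over the list alone), with a median of -0.31: LOX, the actin-binding TAGLN (-1.50 ± 0.065) and the proteoglycan LUM (-1.07 ± 0.048) fell, and ZEB1 (0.18 ± 0.053) and FBN1 (0.16 ± 0.049) rose. The marker list for fibroblasts and smooth muscle shares TAGLN, LUM, ACTA2, PDGFRB and FAP with it, so the 2 lists are not independent. There, 8 of 12 genes fell and 0 rose (0 higher and 8 lower adjusted over the list alone), with a median of -0.62 and CNN1 among those that fell. Camera called both as lower (adjusted p = 2.13e-05 and 1.27e-04), and neither with an estimated correlation (adjusted p = 0.777 with an estimated correlation for each). TAGLN stood at 337 and 295 CPM in the controls and 108 and 115 CPM in the shRNA libraries.

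Epithelial genes fell more often than they rose. Of 18 tested, 8 fell and 1 rose (1 higher and 8 lower adjusted over the list alone; median -0.20). The keratins KRT7 (-0.97 ± 0.055) and KRT8 (-0.44 ± 0.038) fell and the tight junction protein CLDN1 (0.67 ± 0.053) rose. KRT7 overlaps an antisense gene, and counting ignored strand, so its reads cannot be told apart from that gene's. In the collagen and matrix list 12 of 33 genes fell, such as LAMA5 (-1.26 ± 0.091), BGN (-1.26 ± 0.11) and COL5A1 (-0.46 ± 0.048), and 4 rose (6 higher and 15 lower adjusted over the list alone), namely COL6A3 (0.83 ± 0.11), EFEMP1 (0.32 ± 0.038), LAMC1 (0.25 ± 0.040) and LAMA3 (0.27 ± 0.053). Camera called both as lower (adjusted p = 0.0391 and 0.0469), but not with an estimated correlation (adjusted p = 0.782 and 0.787 with an estimated correlation). Fry also called neither (adjusted p = 0.0705 and 0.111 by fry). The epithelial call was lost with a 1 CPM filter (adjusted p = 0.129) or protein-coding genes alone (0.0724), and the matrix call with those (0.0778 and 0.093), with library totals (0.0586) and with GC and length trends removed (0.193). ATAGTGA occurred 1 time in the coding part of COL6A3.

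Adhesion genes moved both ways: 6 of 26 rose and 12 fell (6 higher and 13 lower adjusted over the list alone). ITGA2 rose, and the adhesion molecules L1CAM (-1.33 ± 0.046) and MCAM (-1.05 ± 0.047) fell, without a call by camera (adjusted p = 0.0785; 0.00829 without control 1, 0.0156 without control 2, 0.00323 without shRNA library 2, 0.0101 with DESeq2 and 0.0206 with no filter on low counts). Among 22 matrix proteases and inhibitors, 6 rose and 7 fell (7 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.925): the urokinase PLAU (1.12 ± 0.050) and its receptor PLAUR (0.51 ± 0.050) rose, and the inhibitor TIMP3 (-1.08 ± 0.062) fell. Of 8 fallopian secretory markers tested, 3 fell, KRT7, MSLN (-0.69 ± 0.087) and FOLR1 (-1.19 ± 0.22), and WT1 (0.35 ± 0.078) rose (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.513, 0.0304 without control 2 and 0.0262 without shRNA library 2; 0.0291 with fry). The median lay above 0 and the mean and test direction below. Among 9 ciliated cell markers, MCIDAS (0.76 ± 0.18) rose and the tubulins TUBB4B (-0.40 ± 0.048) and TUBA1A (-0.22 ± 0.042), which have close paralogs and are uncertain, fell (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.921). Median and mean lay above 0 and the test direction below. Of 5 immune markers tested, CSF1R (0.51 ± 0.16) rose and CD14 (-1.93 ± 0.49) fell (1 higher and 1 lower adjusted over the list alone). Camera did not call this list (adjusted p = 0.931), with a median above 0 and a mean and test direction below. CD14 lay at low levels, with means of 0.415 CPM in controls and 0.106 CPM in shRNA cells. The CD14 call was lost without control 2 or either shRNA library, and that of CSF1R without control 1 or either shRNA library, with DESeq2, with no filter and with thinned counts. MCIDAS lost its call with DESeq2 and TUBA1A without shRNA library 1. Of 3 endothelial markers tested, TIE1 (-1.86 ± 0.29) fell and 0 rose (0 higher and 1 lower adjusted over the list alone), too few for a set test, and TIE1 carried ATAGTGA 1 time in its coding part.

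**Figure D4:**
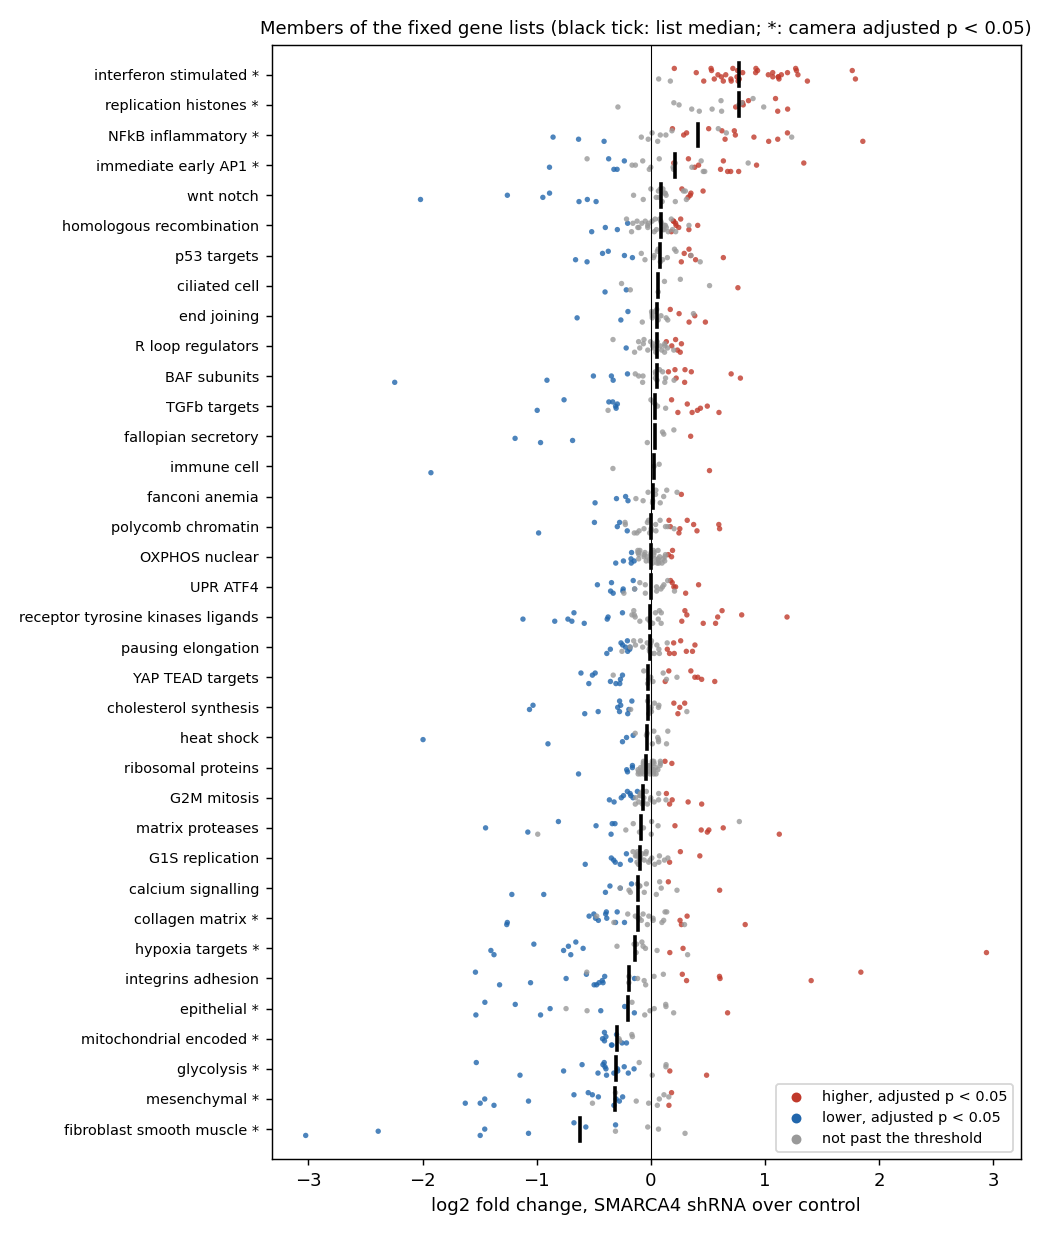
Log2 fold change of shRNA over control cells (x axis) for each tested member of the 36 fixed lists with at least 5 tested members (y axis, ordered by median). Black ticks mark medians and asterisks an adjusted p under 0.05 by camera with a preset correlation of 0.01. The medians run from -0.62 for fibroblast and smooth muscle markers to 0.77 for interferon-stimulated genes. No list was called with an estimated correlation, a setting with little power at 2 libraries per group.

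Transcripts of replication-dependent histones were higher, at low levels. Of 19 tested, 7 rose and 0 fell (8 higher and 0 lower adjusted over the list alone), with a median of 0.77. H2AC6 (1.11 ± 0.10), H1-2 (0.74 ± 0.088) and H2BC21, 2.29-fold higher, led. Histone genes took 0.00370% and 0.00379% of counts in the controls and 0.00663% and 0.00685% in the shRNA libraries, and their near-identical copies make single members uncertain. The libraries were made with an mRNA kit, and how fully it captures histone transcripts was not tested. Camera called the list as higher (adjusted p = 1.13e-04), but not with an estimated correlation (adjusted p = 0.777 with an estimated correlation). Among 32 genes of DNA replication, 3 rose and 7 fell (4 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.0718, 0.0153 without control 2), with MCM6 (-0.58 ± 0.042) and MCM4 (-0.31 ± 0.037) among those that fell. Among 32 mitotic genes, 5 rose, led by HMMR (0.44 ± 0.044), and 9 fell, such as KIF20A (-0.32 ± 0.039) and ANLN (-0.36 ± 0.046) (6 higher and 11 lower adjusted over the list alone; camera adjusted p = 0.130). Both were called as lower with no filter on low counts (adjusted p = 0.0131 and 0.0292) and with GC and length trends removed (0.0428 each). MCM6 carried ATAGTGA 1 time in its 3' UTR.

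In the p53 target list, 6 of 25 genes rose, such as TNFRSF10B (0.39 ± 0.044) and AEN (0.63 ± 0.081), and 6 fell, such as the ubiquitin ligase MDM2 (-0.56 ± 0.046) (8 higher and 6 lower adjusted over the list alone). Unfolded protein response and ATF4 genes were also divided, with 6 higher and 8 lower of 26 (7 higher and 9 lower adjusted over the list alone): EDEM1 (0.30 ± 0.046) rose and ATF4 (-0.25 ± 0.046) and XBP1 (-0.24 ± 0.046) fell. In the heat shock list 5 of 15 fell and 0 rose (1 higher and 6 lower adjusted over the list alone). Those that fell included the small heat shock protein HSPB1 (-0.90 ± 0.053), BAG3 (-0.25 ± 0.048) and CRYAB, at 0.251 of its control level. CRYAB lay at low levels, with 0.915 and 1.08 CPM in the controls and 0.345 and 0.145 CPM in the shRNA libraries. Ribosomal protein genes gave 2 higher and 5 lower of 47 (1 higher and 5 lower adjusted over the list alone), with RPL23 (-0.63 ± 0.043), RPL12 (-0.21 ± 0.037) and RPL28 (-0.21 ± 0.041) falling. Their pseudogenes make them uncertain, and the calls of RPL12 and RPL28 were lost without shRNA library 1. Camera called none of these 4 lists (adjusted p = 0.341, 0.987, 0.253 and 0.175), but without control 2 it called the heat shock list (adjusted p = 0.00134) and the ribosomal list (0.0467, and 0.0428 with no filter on low counts) as lower. MDM2 carried ATAGTGA 1 time in its 3' UTR and 1 time in its coding part.

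Chromatin regulators outside BAF moved both ways, with 9 higher and 5 lower of 31 (11 higher and 9 lower adjusted over the list alone). The Polycomb subunit SUZ12 (-0.98 ± 0.055) fell, with 2 copies of ATAGTGA in its coding part, while the remodeller SMARCA5 (0.40 ± 0.038), with 1 copy there, and JARID2 (0.60 ± 0.059), a cofactor of SUZ12's complex, rose. Calcium genes gave 2 higher and 6 lower of 20 (2 higher and 6 lower adjusted over the list alone): the calcium pump ATP2B4 (-1.22 ± 0.041) and S100A6 (-0.40 ± 0.041) fell and the channel subunit ORAI1 (0.60 ± 0.083) rose. YAP and TEAD targets gave 7 higher and 9 lower of 25 (8 higher and 9 lower adjusted over the list alone), with ARHGEF17 (-0.54 ± 0.053) and TEAD1 (-0.36 ± 0.040), the latter with 1 copy of ATAGTGA in its coding part, falling and WWTR1 (0.44 ± 0.052) rising. TGF-beta targets gave 8 higher and 7 lower of 21 (8 higher and 7 lower adjusted over the list alone), with LTBP2 (0.60 ± 0.047) rising, FN1 (-0.31 ± 0.043) falling and BMP4 falling to 0.501 of its control level. Receptor tyrosine kinases and ligands gave 9 higher and 9 lower of 31 (9 higher and 10 lower adjusted over the list alone), with EPHB2 (-0.58 ± 0.046), FGFR2 (-0.69 ± 0.076) and PDGFB (-1.12 ± 0.13) falling. Wnt and Notch genes gave 5 higher and 7 lower of 28 (6 higher and 7 lower adjusted over the list alone), with DKK3 (-0.63 ± 0.040), WNT10A (-2.02 ± 0.19) and WNT7B (-0.95 ± 0.096) falling. Camera called none of these 6 lists (adjusted p = 0.614, 0.131, 0.925, 0.889, 0.931 and 0.925), and the TGF-beta and Wnt lists had medians and test directions above 0 with means below. Without control 2, the YAP list was called as lower (adjusted p = 0.000522), and so was the calcium list (0.0366, with 0.0262 without shRNA library 2 and 0.0236 with DESeq2).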

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

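SMARCA4 was lower under every alternative run for it, with log2 fold changes of -2.19 to -2.29 over the fits that each left out 1 library. Removing GC and length trends and testing without genes carrying the leading 7-mers were chosen after seeing the data. None of the 5572 genes past the threshold changed sign while past it in another setting. Over all alternatives, results for named genes kept their side of the threshold in 1910 cases, lost it in 31, gained it in 12 and reversed in 0; results for lists did so in 556, 32, 22 and 0. The count of 5572 genes (2596 higher, 2976 lower) was 3187 (1403 and 1784) with no filter, where 35109 genes were tested, and 3555 (1625 and 1930; 103 and 212 with an absolute log2 fold change of at least 1) with DESeq2, which left 2549 adjusted p-values as NA. It was 3139 (1361 and 1778; 114 higher by at least 1) at a threshold of 0.01 and 295 (93 and 202; 67 and 142 by at least 1) with glmTreat. Genes changed by at least 1 numbered 73 higher and 151 lower with a 1 CPM filter, and 119 were higher among protein-coding genes alone; fewer genes were tested in both. Without genes carrying the leading 7-mers, 3697 of 14874 genes were called, 1904 of them lower, with 79 named genes past the threshold against 121. All 83 named genes still tested there kept their side of the threshold, so the drop came from named genes left out. Leaving out each library gave 3801 to 7446 genes, 1724 to 3618 higher and 2077 to 3828 lower; the remaining library of a group of 1 is assumed to vary like the other group. The 192 higher and 366 lower by at least 1 became 149 to 242 and 334 to 494. The 4 lists called higher and 7 called lower became 0 and 0 with an estimated correlation, and 1 and 3 with fry. With fry 8 of these calls were lost and 1 was gained, the secretory list as lower. Fry asks whether a list moves and not whether it moves more than other genes. Camera with an estimated correlation has little power with 2 libraries per group. The interferon list, 35 of 37 of whose members rose, had an unadjusted p of 0.174 by camera with that setting. The lack of calls there therefore does not decide whether lists moved. Lists called lower numbered 11 with no filter, 4 with a 1 CPM filter, 4 with protein-coding genes alone, and 7 to 14 when 1 library was left out, with 14 without control 2. Each fit that left out 1 library called 4 lists higher. The R-loop list was called with library totals (adjusted p = 0.0316) and no filter (0.0433), and lay at 0.0548 to 0.297 when 1 library was left out; pausing lay at 0.645 to 0.970 and homologous recombination at 0.370 to 0.568 there. The cause of these moves was not tested, except where fewer genes or libraries entered. Limma-voom gave nothing separate for lists, since camera already ran on voom values. The labels do not say whether a replicate number marks a shared day or culture. Differences between replicates 1 and 2 correlated across genes at 0.075 between the groups (0.35 in 6333 genes of higher expression). Whether the replicates are paired stays open. With the replicate block 6749 genes were called, including all 5572 and also ARID1A and NELFE, and no list call changed. Thinning to the smallest library gave 5620 genes. Simulated 1.2-fold changes were recovered in 26.0% of genes at these depths and 2 libraries per group. Few genes were changed in that simulation, so this share need not hold for the data. What depth alone limits was not tested.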

Other observations

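4 gene lists were chosen after seeing the data, as were the tests of an active hairpin and of control library 2; the tests of the 7-mer, of GC and length and of each library for the interferon list were written before their results. Genes of the contractile apparatus and targets of SRF fell together, with 1 higher and 23 lower of 30 tested (median -0.41; 1 higher and 24 lower adjusted over the list alone). MYL9 (-1.23 ± 0.054), a myosin light chain, FLNC (-1.11 ± 0.068), TPM2 (-0.76 ± 0.045), ACTA2 (-1.46 ± 0.11), LMOD1 (-1.82 ± 0.18) and SRF itself (-0.89 ± 0.084) were among them. TAGLN, CNN1, ACTA2 and SRF, which fell, also stand in fixed lists, and of the other 26 members 19 fell and 1 rose. No test of these 4 lists as sets is given, since they were picked from the same data. The list's median over the controls' mean was 0.09 and -0.09 in the controls, and -0.41 and -0.39 in the shRNA libraries.

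Nucleic acid sensors gave 10 higher and 2 lower of 16 (median 0.27; 11 higher and 2 lower adjusted over the list alone); ADAR (0.52 ± 0.045), RIGI (0.80 ± 0.074) and DHX58 (1.07 ± 0.16) rose and the adaptor MAVS (-0.49 ± 0.065) and the DNA exonuclease TREX1 (-0.50 ± 0.14) fell. IFIH1 and RIGI of this list also stand in the interferon-stimulated list. Antigen presentation genes gave 7 higher and 1 lower of 20 (7 higher and 1 lower adjusted over the list alone), with the peptide transporter TAP1 (0.58 ± 0.065) and the peptidase ERAP1 (0.42 ± 0.041) rising and HLA-B (-0.17 ± 0.053), which shares reads with its paralogs, falling. Of 9 interferon receptors and kinases tested, 5 rose, such as IFNGR2 (0.87 ± 0.068) and JAK1 (0.44 ± 0.045), and IFNLR1 (-0.37 ± 0.100) fell (5 higher and 2 lower adjusted over the list alone).

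Many genes other than SMARCA4 fell with little spread between libraries, and across 9935 genes the 7-mer of 3' UTRs most closely tied to lower levels was ATAGTGA (t = -13.0, 1150 UTRs, effect -0.13), where 100 permutations reached -5.08 and the best 7-mer sharing no 5 bases with it -5.17. It also led in coding parts (t = -7.44), and the 9 bases assembled from the 3 leading 7-mers, GATAGTGAA, occur 1 time in SMARCA4, in its coding part, where chance gives 2.08%; a candidate explanation is that the hairpin's guide acts through its seed on other transcripts, such as NUCKS1 (-1.31 ± 0.039; 1 copy in the 3' UTR and 3 in the coding part), YWHAG (-1.14 ± 0.045; 2 copies in the 3' UTR), both picked after their values were seen, and SMARCC1. The 7-mer was in the 3' UTR of 19.2% of 2091 genes that fell. It was in 10.2% of 5901 not past the test and in 7.72% of 1943 that rose. The excess over those not past the test was 9.03 points (15.2 among 79 that fell by a log2 fold change of at least 1). For the 3 leading 7-mers together the shares were 31.7% and 18.7%. Among the genes searched, this argues against 3' UTR sites of these 3 7-mers as the direct source of most falls. The search held 2091 of the 2976 genes that fell, and 79 of the 366 that fell by at least 1. Related 7-mers such as AGTGAAA (t = -8.64) also passed the permutations and are not in these shares. With 0, 1, 2 and at least 3 copies in the coding part or 3' UTR, 18.5%, 29.3%, 39.8% and 52.3% of genes fell. Their median log2 fold changes were 0.014, -0.046, -0.049 and -0.186. Unlike the search of 7-mers, this tally was not adjusted for length, GC content or expression. The hairpin's sequence is not given in the sources used here, so which falls follow SMARCA4 loss stays open, for genes with a copy and for genes without.

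Interferon-stimulated genes rose together, by a median of 0.77. With GC and length trends removed the median was 0.770, and the lowest over the fits leaving out 1 library was 0.669, which argue against transcript composition and against 1 library alone. Genes carrying the leading 7-mers left out, 21 of 23 members rose, with a median of 0.91. An active hairpin in the cell, whatever its target, may raise such genes too. The labels name 1 hairpin treatment, so such an effect cannot be told apart from SMARCA4 loss. SMARCA4 loss as the biological explanation stays open and untested.

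Mitochondrially encoded transcripts were lower, by a median of -0.30, and control library 2 had the highest mitochondrial share, 4.06%. Without it the median was -0.159, with quartiles of -0.22 and -0.09. Relative to the mean of the controls, the list's median was -0.16 and 0.16 in controls 1 and 2. It was -0.27 and -0.32 in shRNA libraries 1 and 2. Control 1 alone lay above both shRNA libraries in 12 of 13. The bound of -0.15 was set for the median without control 2. That median lay just below it, which by that rule goes against control 2 as the only source. The quartiles, which were not part of the rule, span the bound, and 1 control remains. Part of the difference may come from control 2, and what remains cannot be told apart from a difference between libraries. Without control 1 the median was -0.44, and a biological explanation was not tested.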
